A study of Mus musculus with 2 samples.

How the data were processed

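Small RNA libraries made from total RNA of mouse skeletal muscle (strain B6NCrl) were counted over miRNA genes. The 2 libraries came from 2 pups of 1 litter at postnatal day 0, named here replicate 1 (pup 1) and replicate 2 (pup 2), and their sex was not collected. The labels put both in 1 group, so no contrast between conditions existed and no p-value for a condition was computed. Each library stands for 1 pup, and differences between pups could not be separated from differences in dissection or library preparation.

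The deposited values were whole-number read counts per miRNA gene, made library by library on build mm10 with the M4 annotation, per the deposited description of each library. The aligner and the counting program were not given in the sources used here. Each deposited count table held 3 columns of counts without a header, and in every gene the first equalled the sum of the other 2. The first column was therefore read as reads on either strand, and the other 2, from their layout and their totals, as reads on the gene's own strand and on the opposite strand. The sources used here do not name the columns. The own-strand column was chosen as the main one before the data were examined. The 4 leading lines of the own-strand column gave reads not counted in a gene on that strand and stayed out of library sizes. In replicate 1 they held 30.2% multimapping, 9.66% unmapped and 7.56% reads without a gene on their own strand. In replicate 2 they held 29.9%, 10.1% and 8.44%. The last of these values includes reads on the strand opposite a listed gene, 415728 of 539809 in replicate 1 and 662868 of 838844 in replicate 2. Reads without a gene on either strand were 124081 and 175976.

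Of 1973 listed genes, 1894 were matched by identifier to GENCODE M21, an annotation of the same genome build, which supplied names, coordinates and host genes. The remaining 79 had fewer than 10 counts in each library. A place is called exonic where at least 1 transcript of the host gene has an exon there.

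Own-strand gene counts were scaled to CPM by the library's own-strand total. Ratios between the libraries used edgeR 4.0.16 TMM factors (1.05 and 0.954) in R 4.3.3, with 0.5 added to each count, and are given as log2 of replicate 2 over replicate 1. Against total-count scaling the TMM factors shifted every log2 ratio by 0.13. Each gene with at least 10 counts in total was tested with an exact two-sided binomial test given the scaled library sizes, with Benjamini-Hochberg adjustment, a threshold of 0.05 and at least 2-fold. This test compares 2 libraries beyond counting error. The biological coefficient of variation was the square root of edgeR's common dispersion. Shares have exact Clopper-Pearson 95% intervals from scipy 1.17.1. A gene with 0 counts could hold up to 3 counts, which is 0.799 CPM in replicate 1 and 0.584 CPM in replicate 2. Reads carried no molecular identifiers in these tables, so intervals and floors cover counting error only.

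A total of 20 gene lists was fixed before the data were examined, covering muscle, imprinted, cluster, cell type and multi-locus miRNA genes. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean CPM. The named genes were all members of the muscle list, the 15 genes with the highest mean CPM, the 3 most abundant members of every other list, and up to 5 genes per direction with the largest called ratio and a mean of at least 100 CPM. A gene named outside this rule is said to have been chosen after its values were seen.

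The procedures were tested on simulated counts for 392 genes drawn from these libraries. Recovery required an adjusted p under the threshold and the simulated direction, without the 2-fold minimum. Of genes changed 2-fold, 46 of 60 were recovered in this sense, and of genes changed 4-fold, 52 of 63. These rates do not describe the calling rule, which adds the 2-fold minimum. Among 4-fold genes with at least 100 counts, 36 of 36 passed the threshold on adjusted p in either direction. With the 2-fold minimum added, 0 of 269 unchanged genes were called. The simulated libraries differed by Poisson counting error alone, as the test assumes. The simulation therefore gives no rate of false calls between pups. Alternatives were the count of both strands, other filters on low counts, DESeq2 1.42.0 size factors, total-count scaling, other denominators and pseudocounts, each library alone, and lists without multi-locus genes. Crediting opposite-strand counts to the miRNA gene annotated on that strand was added after seeing the data.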

Results

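The miRNA content of newborn mouse skeletal muscle was measured in 2 libraries from littermates at postnatal day 0. Replicate 1 held 3754895 own-strand counts in miRNA genes and replicate 2 held 5133949, which were 52.6% and 51.6% of all reads. At least 10 counts were found in both libraries for 311 miRNA genes, and 1320 of the 1973 listed genes had 0 counts in both. Counts were concentrated. The 10 most abundant miRNA genes held 50.7% ± 1.91 (SD, n = 2) of all counts, and 22 genes had a mean of at least 10000 CPM. All means below are over these 2 libraries.

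Mir206, a miRNA of skeletal muscle, had the highest own-strand count of the listed genes, 83323 ± 5480 CPM (SD, n = 2). Reads that map to several places, 30.2% and 29.9% of all reads, were listed apart from the gene counts, so all ranks here leave them out. It lies on chromosome 1 from 20679010 to 20679082 (mm10, plus strand), in an exon of the non-coding gene Gm28653. The 9 measured genes of the striated muscle list, out of 10 listed, held 8.13% of counts in replicate 1 (95% interval 8.11 to 8.16, Clopper-Pearson) and 8.94% in replicate 2 (8.91 to 8.96), nearly all of it from Mir206. Mir133b, in the same host gene at 20682769 to 20682887, had 773 ± 130 CPM. The miRNA genes inside introns of myosin heavy chain genes were lower: Mir499 in Myh7b had 599 ± 37.9 CPM, Mir208b in Myh7 had 564 ± 5.05 CPM, and Mir208a in Myh6 had 10.9 ± 3.34 CPM. Mir486, in an intron of Ank1, had 70.8 ± 13.1 CPM. Mir1a-1 had 24 and 46 counts, Mir133a-1 had 20 and 32, and Mir133a-2 had 4 and 6. These 3 genes and Mir133b share a stretch of at least 20 bases with another miRNA gene, and their counts are uncertain for that reason. Mir1a-2 was not among the listed genes.

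The imprinted Dlk1-Dio3 cluster on distal chromosome 12 held the largest share of the 20 lists, 35.8% of counts in replicate 1 (35.7 to 35.8) and 41.7% in replicate 2 (41.7 to 41.8). Of 49 genes fixed for it, 43 were measured and 42 had at least 10 counts in both libraries. Mir487b (109727333 to 109727414), outside any annotated host gene, had 58765 ± 5966 CPM. Mir431 followed with 55081 ± 8593 CPM, Mir127 with 53520 ± 3573 CPM, Mir411 with 52132 ± 5067 CPM, Mir381 with 45041 ± 8319 CPM and Mir379 with 19962 ± 986 CPM. Mir487b and Mir411 also share a stretch of at least 20 bases with another miRNA gene, so their counts are uncertain as well. Other imprinted loci were also represented. Mir335, in an intron of Mest on chromosome 6, had 51246 ± 7725 CPM. Mir483, in an intron of Igf2, had 8193 ± 1711 CPM, and Mir675, in an exon of the H19 RNA, had 127 ± 13.0 CPM. Together the Igf2 and H19 genes held 0.710% and 0.954% of counts.

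The let-7 family, which accumulates as tissues differentiate, held 8.70% of counts in replicate 1 and 7.74% in replicate 2, with 10 of 12 genes measured. Mirlet7i had 32280 ± 2655 CPM, Mirlet7g, in an intron of Wdr82, had 30200 ± 2513 CPM, and Mirlet7d had 11273 ± 236 CPM. Some other members share a stretch of at least 20 bases with another miRNA gene. Among them Mirlet7a-1, chosen after its values were seen, had 99.9 ± 25.3 CPM. Reads that map to several places are left out, so the family's share and the order of its members are uncertain. The X-linked cluster of Mir322 and Mir503, linked to myoblast differentiation, held 5.06% and 4.51%. Within it, Mir322 (chromosome X, 53054255 to 53054349, minus strand) had 29178 ± 1772 CPM, Mir351 had 13390 ± 1892 CPM and Mir542 had 2677 ± 54.8 CPM. The proliferation-linked clusters led by Mir17 held 1.09% and 0.810%, with Mir17 at 3681 ± 969 CPM, Mir20a at 1263 ± 383 CPM and Mir18 at 1149 ± 82.6 CPM. The 6 genes inside the Hox clusters held 2.28% and 1.96%, with Mir10b at 8906 ± 540 CPM, Mir196b at 8523 ± 1310 CPM and Mir10a at 1953 ± 267 CPM. Some members of the Mir17 and Hox lists have a mature sequence made from several loci, so these shares are uncertain as well. The Mir29 family held 0.0264% and 0.0250%, with Mir29a at 180 ± 16.9 CPM, Mir29c at 74.8 ± 8.25 CPM and Mir29b-1 at 1.29 ± 0.441 CPM. Mir29b-1 also shares a stretch of at least 20 bases with another miRNA gene, so its count is uncertain.

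Genes of the lists named for other cell types were present at very different levels. A list describes levels in bulk tissue, so a share does not show which cells the counts came from. The endothelial gene Mir126a, in an exon of Egfl7, had 38672 ± 2989 CPM. The fibroblast and smooth muscle list held 4.57% and 4.21% of counts, led by Mir143 at 30088 ± 137 CPM, Mir21a at 7078 ± 1974 CPM and Mir214 at 5831 ± 590 CPM. Genes of the neural list held 0.135% and 0.158%, with Mir128-1 at 629 ± 102 CPM, Mir128-2 at 456 ± 79.9 CPM and Mir338 at 368 ± 13.4 CPM. Of the 12 measured, 4 had 0 counts in both libraries. Some neural genes, Mir128-1 and some of those with 0 counts among them, have a mature sequence made from several loci. Reads that map to several places are left out, so the neural share is uncertain. White blood cell genes held 0.0646% and 0.0458%, with Mir223 at 420 ± 120 CPM, Mir146 at 59.6 ± 1.62 CPM and Mir155 at 44.9 ± 9.54 CPM. Mir142, 1 of the 5 genes of that list, was not among the listed genes, and crediting it with the opposite-strand counts at its place raised the list's mean share from 0.0552% to 0.114%. Red blood cell genes held 0.0416% and 0.0299%, with Mir451a at 271 ± 91.6 CPM and Mir144 at 87.0 ± 8.91 CPM. The liver gene Mir122 had 182 ± 3.59 CPM. Endocrine and pancreatic genes held 0.00684% and 0.00423%, with Mir375 at 31.7 ± 15.4 CPM, Mir7-1 at 20.2 ± 3.47 CPM and Mir7b at 1.74 ± 0.573 CPM. Some genes of this list and of the fibroblast and smooth muscle list have a mature sequence made from several loci, so both shares are uncertain. Pluripotency genes held 0.00115% and 0.000390%, and Mir293, Mir302d and Mir294 had at most 10 counts per library. Loci that resemble ribosomal RNA held 0.00224% and 0.00267%, with Mir6236 at 17.3 ± 2.58 CPM, Mir6240 at 6.35 ± 0.438 CPM and Mir2137 at 1 and 8 counts. Mir99a at 36446 ± 4535 CPM and Mir23a at 19315 ± 787 CPM completed the 15 most abundant genes by own-strand counts, a ranking that leaves out the opposite-strand counts at the places of Mir378a (57661 CPM) and Mir376a (22045 CPM).

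**Figure D1:**
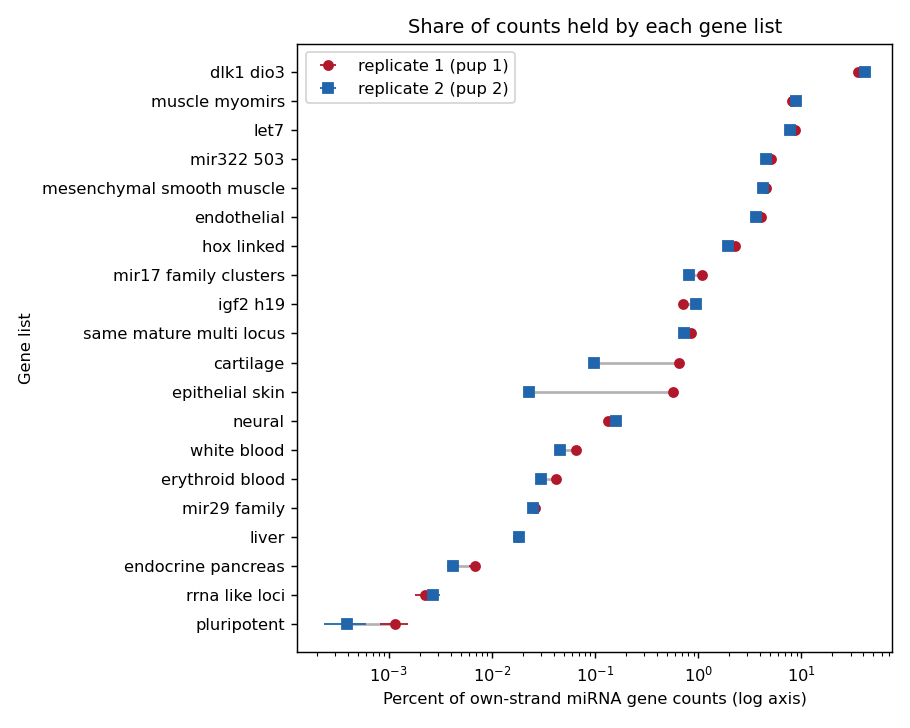
Each point is the percent of own-strand miRNA gene counts held by a gene list in 1 library, on a log axis, with the exact 95% interval of counting error as a horizontal line and a grey line joining the 2 libraries. The cartilage list (0.654% against 0.0966%) and the epithelial list (0.569% against 0.0230%) lie apart between the libraries.

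The 2 libraries were close for most genes. Over 337 genes with at least 10 counts in either library, Pearson's r of log2(CPM + 1) was 0.983 and Spearman's rho 0.980, across genes, which are not independent replicates. Of the 311 genes with at least 10 counts in both, 296 differed by less than 2-fold, and the biological coefficient of variation was 0.319. The libraries were not copies of each other, since a chi-square of their counts was 281 times its degrees of freedom. Of 373 genes tested, 17 were at least 2-fold higher in replicate 1 and 2 were at least 2-fold higher in replicate 2 beyond counting error (exact binomial test, adjusted p under the threshold). Without the 2-fold minimum, 86 were higher in replicate 1 and 97 in replicate 2. The 2 higher in replicate 2, Mir378d and Mir3100, had means of 20.7 and 4.16 CPM and were chosen after their values were seen.

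Genes of epithelia and skin were much higher in replicate 1. All 7 list members were called, and 7 were called when adjusted over the list alone. Their share was 0.569% (0.561 to 0.576) in replicate 1 and 0.0230% (0.0217 to 0.0243) in replicate 2, a ratio of 24.8. Mir205 (chromosome 1, 193507463 to 193507530) had 3167 counts in replicate 1 and 92 in replicate 2, Mir203 (chromosome 12, 112130880 to 112130955) had 16356 and 938, and Mir429 had 710 and 50. The list's median log2 ratio was -4.13, below all 10000 random lists. Several of the 7 lie within 10 kb of another member, so they are not independent, while the random lists drew single genes. Mir140, a cartilage miRNA in an exon of Wwp2 (chromosome 8, 107551244 to 107551313), had 24555 and 4959 counts, a log2 ratio of -2.62. Mir182 had 833 and 267 counts, and Mir708, in an intron of Tenm4, had 2714 and 1352. Means of the epithelial list and of Mir140 therefore rest on replicate 1.

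Several other lists differed between the libraries, most of them by less. In the Dlk1-Dio3 cluster 41 of 42 tested genes had a higher value in replicate 2, with a median log2 ratio of 0.36 (percentile 100 of the random lists). The random lists drew single genes, while these 42 lie in 1 cluster and are not independent. Beyond counting error, 36 were higher and 1 was lower, all by less than 2-fold, so 0 were called over all genes or adjusted over the list alone. All 9 muscle genes had a higher value in replicate 2, with a median of 0.35 (percentile 98.3). For 6 of them the difference exceeded counting error, with 0 at 2-fold over all genes or adjusted over the list alone. Mir206 and Mir133b share a host gene, so the 9 are not all independent, while the random lists drew single genes. Settings were compared over 2000 random lists, where the muscle percentile was 97.8 in the main setting. Counting both strands moved it to 97.0, and crediting opposite-strand counts, which gave 10 tested genes, to 95.7. The values of 97.0 and 95.7 lie inside the central 95% of random lists. The median of the Igf2 and H19 genes was 0.45 (percentile 99.1), over only 2 genes, Mir483 and Mir675. Both lie on chromosome 7 and may not be independent, while the random lists drew single genes. In the let-7 family 9 of 10 genes had a lower value in replicate 2, with a median of -0.25 (percentile 0.330) and 0 calls by either adjustment. The differences of these 9 and of the 1 higher gene exceeded counting error, all by less than 2-fold. Without multi-locus genes the let-7 median was -0.035. The fibroblast and smooth muscle list had a median of -0.27 (percentile 1.71), which was -0.072 without multi-locus genes. The pluripotency list had a larger median of -2.39 (percentile 0.350), over only 3 of its 11 measured genes. These 3 had at least 10 counts in total and at most 10 per library. Of these, 2, Mir294 and Mir293, were called higher in replicate 1, as were 2 when adjusted over the list alone. Mir293 (10 and 2 counts) and Mir294 (9 and 1) reached the minimum mainly through replicate 1. Mir126a and Mir122, each the only gene of its list, had log2 ratios of -0.023 and 0.17. The Hox, neural, blood, pancreatic, Mir29, Mir17, Mir322 and ribosomal-like lists lay within the central 95% of their random lists. The neural list held 1 called gene, also called when adjusted over the list alone: Mir129-2, chosen after its values were seen, had 22 and 10 counts and a log2 ratio of -1.42.

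**Figure D2:**
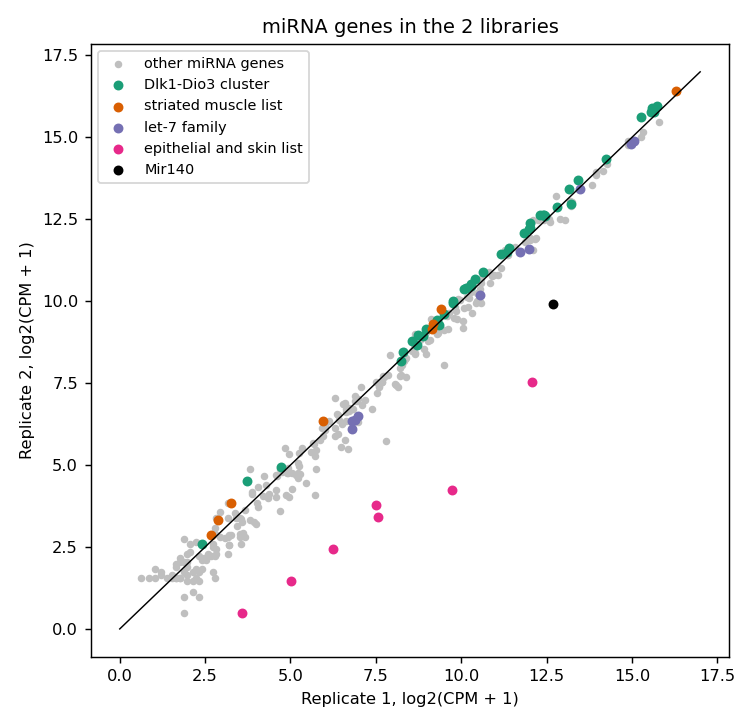
Each point is 1 of the 337 miRNA genes with at least 10 counts in either library, placed by log2(CPM + 1) in replicate 1 (horizontal) and replicate 2 (vertical), with a line of equal values. The 7 epithelial genes and Mir140 lie below the line, while Dlk1-Dio3 genes lie mostly just above it.

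Genes whose mature sequence is made from several loci had few counts. The 50 measured members of that list, out of 54, held 0.859% of counts in replicate 1 and 0.735% in replicate 2. Their most abundant members were Mirlet7f-2 at 1335 ± 243 CPM, Mir92-1 at 910 ± 2.56 CPM and Mir16-1 at 871 ± 273 CPM. The list had a median log2 ratio of -0.29 (percentile 0.280).

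Reads on the strand opposite a listed gene made up 9.97% of gene counts in replicate 1 and 11.4% in replicate 2, and 99.8% of them fell on 9 loci. The highest was the place of Mir378a (chromosome 18, 61397835 to 61397900, minus strand), which was not itself among the listed genes.

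**Figure D3:**
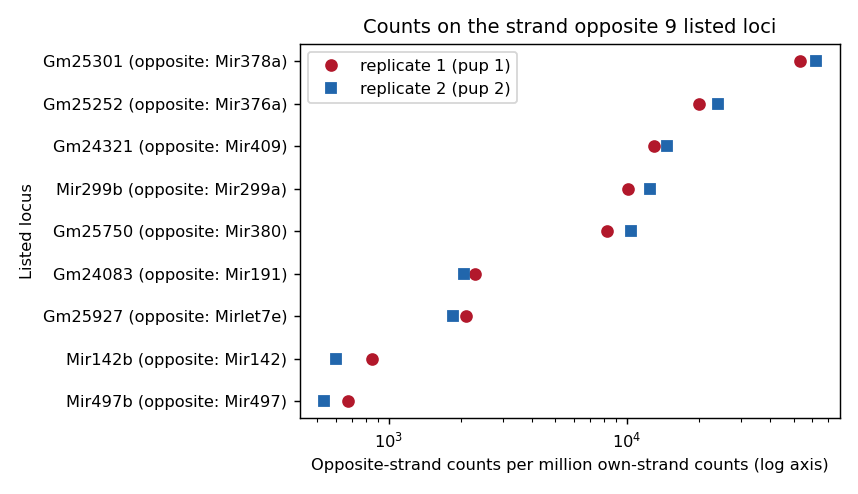
Each point is the opposite-strand count at 1 of the 9 loci in 1 library, in CPM of own-strand counts, on a log axis, with the miRNA gene annotated on that strand in brackets. Values run from 535 opposite Mir497b to 62069 opposite Gm25301, both in replicate 2.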

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

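The tests of opposite-strand counts and of multi-locus genes were chosen after the values were seen. No biological explanation was tested for the opposite-strand counts, since the labels give 1 group.

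Counts on the strand opposite 9 listed loci were not used in the main values, and they lay above the limit that a count of 0 allows. In CPM of own-strand counts, they averaged 57661 opposite Gm25301, 22045 opposite Gm25252, 13824 opposite Gm24321, 11253 opposite Mir299b, 9342 opposite Gm25750, 2184 opposite Gm24083, 1986 opposite Gm25927, 726 opposite Mir142b and 603 opposite Mir497b. Own-strand counts were 0 in both libraries at 8 of the 9 loci, and Mir299b had 22 and 33. In GENCODE M21 the other strand at these places carries Mir378a, Mir376a, Mir409, Mir299a, Mir380, Mir191, Mirlet7e, Mir142 and Mir497, in that order. A library that does not keep strand is argued against, because genes without such an overlap held 0.00158% of their counts on the opposite strand. A candidate explanation is that reads of these miRNAs were counted against the overlapping listed gene, since 99.99% of opposite-strand counts fell on genes that overlap a miRNA gene on the other strand.

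Reads that map to several places made up 30.0% of all reads on average and were listed apart from the gene counts. Genes that share an identical stretch of 20 bases with another miRNA gene had a median log2 ratio of -5.81 to their highest unique neighbour on the same strand within 10 kb, over 25 genes. Not all were low, since Mir487b (58765 CPM) and Mir411 (52132 CPM) lay above their neighbours by 0.38 and 1.38, and all listed genes with such a copy held 15.8% and 17.1% of counts. Multimapping reads left out of the counts, low transcription of these loci and ordinary differences between neighbours cannot be told apart here. The neighbours had a median of 5831 CPM, but they were chosen as the highest nearby, and those of genes without a copy had 3801 CPM. The bound of -2 set for the log2 ratio was also passed by 106 genes without a copy, whose median was -2.50, with 18.9% of them below the median of the copies, while with at least 10 counts required in both libraries the medians were -5.33 for copies and -1.77 for genes without one.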

How the results depend on the processing

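Opposite-strand crediting was chosen after seeing the data. No result changed direction among lists outside the central 95% of random lists, and counts of called genes ran from 13 to 22 around the main 19. Requiring 1 count raised the genes detected in both libraries to 515, and requiring 50 counts lowered the correlation to 0.973. Over all reads, the muscle share was 4.45%, let-7 4.28%, Dlk1-Dio3 20.2%, multi-locus genes 0.416% and the 10 most abundant genes 26.4%, because the denominator grows. Counting both strands gave 7.62% for muscle, 7.34% for let-7 and 47.5% for the 10 most abundant genes, and crediting gave 7.62%, 7.53% and 47.5%. Without Mir206 the muscle share was 0.222% and let-7 8.96%. Total-count scaling, which shifts all ratios alike, gave list medians of 0.21 for muscle, -0.38 for let-7, 0.22 for Dlk1-Dio3 and -2.76 for Mir140. Leaving multi-locus genes out gave -0.035 for let-7, so its shift rested on those members, and moved the fibroblast and smooth muscle median from -0.27 to -0.072. Either library alone gave epithelial shares from 0.0230% to 0.569%; with 2 libraries such a value always lies within 1 SD of the mean, so this comparison cannot show instability. Among lists inside the central 95%, medians changed sign under total-count scaling for Mir322 (-0.030) and neural (-0.074), and without multi-locus genes for Mir29 (0.15) and neural (-0.28). No paired analysis was possible because there was 1 group. Depth limits genes under about 10 counts.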

Other observations

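The test of further epithelial genes was set before their values were seen, and the test of scaling was chosen after.

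Other miRNA genes known from epithelia and sensory tissue, outside the fixed list, were divided. Mir183 (384 counts in replicate 1 and 224 in replicate 2) and Mir96 (196 and 83) were called higher in replicate 1, with log2 ratios of -1.09 and -1.55, as was Mir182 at -1.96. Mir31 (179 and 211 counts) and Mir184 (19 and 20) had scaled log2 ratios of -0.080 and -0.24. Mir455, in an intron of the cartilage collagen gene Col27a1 and chosen after its values were seen, had 5172 and 5061 counts, a log2 ratio of -0.35 beside -2.62 for Mir140.

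The higher epithelial list in replicate 1 is not accounted for by library size or scaling, since these shift the ratios of all genes alike. In the test chosen for this, at least 95.8% of 306 genes outside the list differed by less than 2-fold under each of 3 scalings. That test adds little, since 296 of 311 genes were already known to differ by less than 2-fold. Epithelial or skin tissue in the muscle piece of pup 1 is a possible explanation, and it stays open. The 4 further epithelial genes had a median log2 ratio of -0.67, between the bound of -1 set for this explanation and the bound of -0.5 set against it. That median is the midpoint of Mir183 and of Mir184, which had only 19 and 20 counts. Mir183 and Mir96 each lie within 10 kb of Mir182, so the 4 are not independent. A difference between the pups themselves was not tested.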
